A study of Drosophila melanogaster with 4 samples.

How the data were processed

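Chromatin from the heads of adult Oregon-R flies, a wild-type laboratory strain of Drosophila melanogaster, was immunoprecipitated with an antibody against LSD1, and the DNA was sequenced together with input chromatin that had not been precipitated. The series held 2 ChIP and 2 input samples, numbered as replicates 1 and 2 in each group, and their labels gave 1 list of enriched regions to each ChIP sample. The labels of each input sample named the list of the ChIP sample with the same number, so the replicate lists were taken as calls of each ChIP library against its own input. A combined list of the replicate set was also used. The labels describe population cages and sieved heads but do not say whether the replicates came from separate collections, so the spread between them may be technical.

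The submitters' processing notes name Bowtie 0.12.7, a short-read aligner. Per the file headers, positions refer to release 5 of the fly genome, and the features are regions of significant enrichment. The region caller, its threshold, the scaling between ChIP and input, and the way the combined list was made are not given in the sources used here. The number of reads per library is likewise not given in the sources used here, so no interval that needs the depth is reported for single regions, and counting error could not be separated from other differences between the lists.

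The deposited score of each region was read as a log2 enrichment of ChIP over input, although no header names its scale. This reading rests on the values. After removal of 1 constant per list, 2 raised to the score was a ratio of whole numbers in 8110 of 8115 regions of replicate 1, in all 9911 of replicate 2 and in 10988 of 11016 of the combined list, at a relative tolerance of 1e-12 and with denominators up to 6000. When a small random amount was added to every score, 0, 1 and 2 regions of these lists still gave such a ratio. The numerator and denominator of each ratio in lowest terms were used only for the comparison of chromosomes and in the closing observations, and what they count is not given in the sources used here. Scores are the authors' values and were used to describe and rank regions within a list. Because each list carries its own constant, differences in score between lists are differences in deposited values and not in occupancy.

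The combined list also held 3 entries typed as depletion, which were left out of all counts of enriched regions. Lengths of the 14 sequences came from the file headers and summed to 168.7 Mb, of which the 6 arms 2L, 2R, 3L, 3R, X and 4 made up 120.4 Mb. The remaining sequences were the Het contigs, which are heterochromatic pieces placed near their arms, and U and Uextra, which hold unplaced sequence. Autosomes are the 4 arms 2L, 2R, 3L and 3R. Chromosome 4, a small and largely heterochromatic autosome, was kept apart.

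The gene table supplied with the data follows release 6 and the lists follow release 5, so no region was assigned to a gene. For this reason 3 planned results, namely position relative to genes, promoter occupancy of gene lists and occupancy by gene class, were not run, and regions are given by coordinates. The tests, the alternatives and the rule for naming regions were fixed before the data were examined, except where a later choice is stated. The rule took the 20 combined regions with the highest score among those overlapped by a region of both replicates, the 3 longest combined regions, and the 3 highest-scoring regions of either replicate without overlap in the other.

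Regions of different lists were called overlapping when they shared at least 1 bp. The overlap share was compared with 1000 circular shifts of 1 list within each sequence, which keep the widths and spacing of its regions, and a one-sided permutation p was taken from them. The smallest p that 1000 shifts can give is 0.001. Shifted shares for regions of at least 10 kb and 20 kb were added later and carry no p. Values for 15 subsets (arms, and 4 equal parts of the list by score and by width) were adjusted by the Benjamini-Hochberg method in each direction of the comparison. Scores were compared over pairs of overlapping regions, each region of replicate 1 being paired with the replicate 2 region of longest overlap. A replicate 2 region could be the partner of several replicate 1 regions. Correlations of these scores are across regions, which are not independent replicates, and carry no p. Intervals at 95% for correlations and for ratios between X and autosomes came from 2000 bootstrap draws of 1 Mb bins, and those for shares of the combined list are Wilson intervals that cover counting of regions only. Values from both replicates are given as mean ± SD with n = 2. No test between chromosomes was run over the replicates, since a two-sided exact sign-flip test of 2 values cannot give a p below 0.5.

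Alternatives were an overlap of at least 50% of the region, a reciprocal overlap of at least 50%, the upper 50% and upper 25% of regions by score, random placement in place of shifts, merging of regions within 500 bp, pairing by highest score, covered length in place of number of regions, each replicate left out in turn, and combined regions overlapped by both replicates. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The overlap test was tested on simulated data built from the 8115 regions of replicate 1. It called 2.5% of lists placed at random at a one-sided p of 0.05. With a known part of the regions planted in both lists, it returned an overlap of 77.0%. The share expected from planted regions and random overlap together was 76.6%, so the planted share itself was lower. These simulated lists were few, used fewer shifts than the real comparison and were placed without the clustering of real regions. Calibration for lists that share such clustering was therefore not tested. The search for whole-number ratios recovered 99.96% of 8115 simulated ratios.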

Results

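LSD1 is a histone demethylase, encoded in flies by Su(var)3-3, that acts on chromatin together with CoREST and histone deacetylases. Its occupancy was measured by ChIP-seq in head chromatin of wild-type adult flies, with 2 ChIP libraries and 2 input libraries. The data comprised 3 lists of enriched regions: replicate 1, replicate 2 and the combined list, each region carrying the authors' score, read as log2 enrichment over input. No second genotype, tissue or treatment was included, so the comparisons are those between the replicate lists, between each replicate and the combined list, and between chromosomes.

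The first question was where LSD1 was enriched and over how much of the genome. Enriched regions covered more than 25% of the length of the 6 chromosome arms in each replicate. Replicate 1 had 8115 regions that spanned 32.6 Mb over all sequences and covered 26.9% of the arms, and replicate 2 had 9911 regions that spanned 33.5 Mb and covered 27.7% of the arms. The combined list had 11016 regions that spanned 44.5 Mb and covered 36.8% of the arms. Median widths were 2187 bp in replicate 1, 2114 bp in replicate 2 and 2025 bp in the combined list. The median score was 0.70 in replicate 1 (1.62-fold), 0.83 in replicate 2 (1.78-fold) and 0.51 in the combined list (1.42-fold). Broad domains stood beside these narrow regions. Regions of at least 10 kb numbered 614 in replicate 1 and held 35.1% of its covered length, and numbered 442 in replicate 2, with 21.0%. Of the 614 broad regions of replicate 1, 589 (95.9%) were covered over at least 50% of their length by replicate 2, where shifted lists gave 21.9% ± 1.98 (SD over 1000 shifts). Of the 442 of replicate 2, 430 (97.3%) were so covered by replicate 1, against 21.7% ± 2.35 for shifted lists. Regions of at least 20 kb numbered 175 in replicate 1 and 78 in replicate 2, and all of them were so covered, against 19.7% and 19.5% for shifted lists.

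The 20 highest-scoring combined regions found in both replicates included 11 on the autosomes, 5 on Het contigs or U, 3 on chromosome 4 and 1 on X, and 6 of the 20 were at least 10 kb wide. The region with the highest combined score among those overlapped by both replicates was 4:1296144-1298594, with a score of 2.42 (5.36-fold), and scores of 2.74 in replicate 1 and 1.97 in replicate 2. A further pair of regions of the same arm also ranked among the 20 highest. These were 4:1315506-1317876 (1.93 combined, 2.12 in replicate 1, 1.64 in replicate 2) and 4:1290080-1292312 (1.66 combined, 2.04 and 1.17). The domain at 2L:6073130-6093832, 20.7 kb wide, scored 2.01 in the combined list and 2.02 ± 0.056 in the replicates (SD, n = 2). A domain of 26.3 kb at 2R:5428688-5454944 scored 1.88 combined and 1.92 in each replicate. On 3R, the domain at 5901878 to 5927056 (25.2 kb) scored 1.72 combined, 1.73 in replicate 1 and 1.76 in replicate 2, and that at 12030054 to 12087772 (57.7 kb) scored 1.73 combined, 1.96 in replicate 1 and 1.53 in replicate 2. At the latter, replicate 2 showed 4 separate regions where replicate 1 had a single region, and the replicate 2 score is that of a region of 43580 bp. The domain at 2L:158264-183312 (25049 bp) scored 1.63 in the combined list, 1.76 in replicate 1 and 1.44 in replicate 2. The single X-linked member of the 20 was X:1973486-1986200 (12.7 kb), with 1.63 combined, 1.74 in replicate 1 and 1.65 in replicate 2. Replicate 2 had 2 regions there, and its score is that of a region of 8670 bp.

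Narrow autosomal regions among the 20 differed in how far apart the deposited scores of the replicates were. Each list carries its own constant, so close scores are not by themselves agreement in occupancy. The regions 2L:20119922-20122978 (1.88 in replicate 1, 2.00 in replicate 2) and 2L:16048692-16050874 (1.94 and 1.77) had close scores. Scores were further apart at 3R:25867844-25870076 (2.18 and 1.24), 3R:18187082-18189426 (1.91 and 1.35), 2R:19920330-19922806 (1.91 and 1.39) and 2R:19954998-19957616 (1.95 and 1.52). Heterochromatic and unplaced sequence also held wide gaps, with 2.57 and 1.00 at U:3442002-3444294, 2.53 and 1.06 at 3RHet:1767470-1770280, 2.22 and 1.21 at U:1101142-1105120, and 2.13 and 1.45 at 3LHet:680626-683004. The region 3RHet:1822586-1825292 had closer scores, at 1.78 and 1.59. Of these 20 selected regions, 18 scored higher in replicate 1, whereas replicate 2 had the higher score in 75.2% of all 6128 overlapping pairs.

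The longest combined regions were 3R:5680112-5809930, 3L:19135566-19231088 and 3L:734540-825308, of 129.8, 95.5 and 90.8 kb. Their combined scores were 1.20, 0.83 and 1.50. The third was listed nearly whole in both replicates, with a region of 86334 bp in replicate 1 and of 88565 bp in replicate 2, whereas the first was split into 3 regions in replicate 1 and 8 in replicate 2, and the second into 8 in each. Some regions with high scores were listed in a single replicate. In replicate 1 these were U:2096500-2097916 (3.31), U:3915942-3917300 (3.21) and 2RHet:2283332-2285694 (3.06), of which only the last was overlapped by a combined region, at 1.51. In replicate 2 they were X:11367565-11370055 (1.62), U:5831900-5833707 (1.59) and 2L:15717358-15718876 (1.56). The X and 2L regions were overlapped by combined regions at 0.69 and 0.70, and the U region by none.

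**Figure D1:**
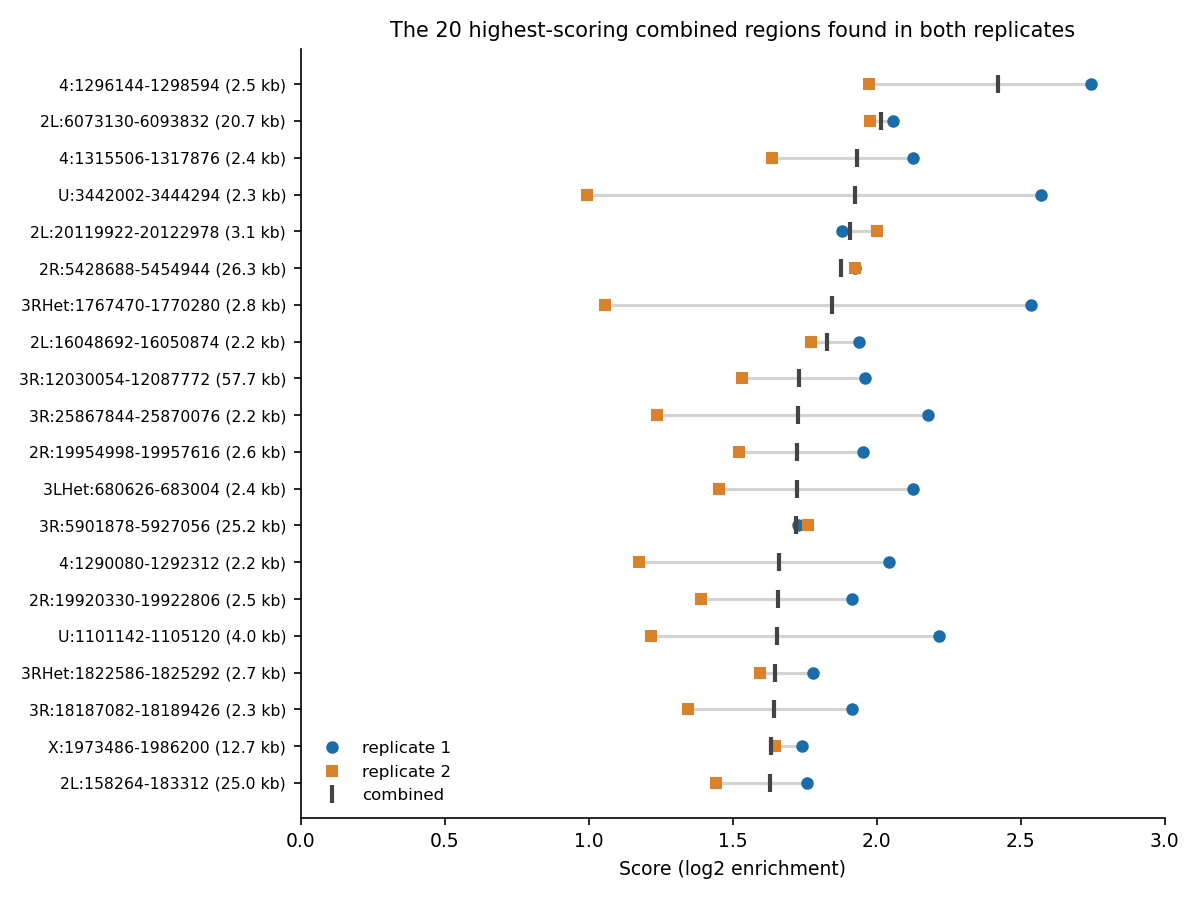
Scores (log2 enrichment, horizontal axis) of the 20 highest-scoring combined regions that were overlapped by both replicates, with replicate 1 as circles, replicate 2 as squares, the combined score as a vertical tick and the gap between the replicates as a grey line. Replicate 1 was higher in 18 of the 20, and the gap was widest at U:3442002-3444294 (2.57 and 1.00). Over all 6128 overlapping pairs, replicate 2 was higher in 75.2%.

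The comparison of the replicate lists asked how far enriched positions recurred. Of the 8115 regions of replicate 1, 6128 (75.5%) were overlapped by replicate 2, where shifted lists gave 44.4% ± 0.647 (SD over 1000 shifts). Of the 9911 regions of replicate 2, 7007 (70.7%) were overlapped by replicate 1, against 41.0% ± 0.676 for shifted lists. The observed shares were 1.70 and 1.72 times the shifted ones, with a one-sided permutation p of 0.001 in each direction, the smallest value that the shifts can give. Shared sequence amounted to 23.2 Mb, a Jaccard index of 0.540, and made up 71.1% of the covered length of replicate 1 and 69.2% of that of replicate 2.

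Autosomes and X differed in which replicate had more regions of its own. On 2L, 2R, 3L and 3R, 78.2% to 81.3% of replicate 1 regions were found in replicate 2, and 66.6% to 71.1% of replicate 2 regions in replicate 1. On X the order was the opposite, with 61.4% of replicate 1 regions found in replicate 2 (36.1% when shifted) and 80.1% of replicate 2 regions found in replicate 1 (42.1% when shifted). Chromosome 4 followed X, at 58.1% of 86 regions and 90.6% of 64 regions. Het contigs and U gave 57.7% of 71 regions and 91.8% of 49 regions, where shifted lists gave 1.90% and 2.98%. Those shifts ran over the full length of the sequences, whose alignable part is not known, so these shifted shares may be too low. Each of the 15 subsets passed in both directions, with one-sided permutation p between 0.001 and 0.005 and Benjamini-Hochberg values of at most 0.005 over the 15. Differences between arms in these shares were not tested.

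The share of recurring regions differed more between narrow and wide regions than between low and high scores. When replicate 1 was divided into 4 equal parts from the narrowest to the widest regions, 52.3%, 68.8%, 84.3% and 96.7% of regions were found in replicate 2, and shifted lists gave 36.6%, 39.0%, 42.3% and 59.7%, so that the ratio to shifted lists was 1.43, 1.76, 1.99 and 1.62. The same parts of replicate 2 gave 46.6%, 61.2%, 80.0% and 94.95%. From the lowest to the highest scores, the 4 parts of replicate 1 gave 74.96%, 74.0%, 72.6% and 80.5%, where shifted lists gave 40.1%, 42.3%, 45.0% and 50.0%, and the ratio went from 1.87 to 1.61. Those of replicate 2 gave 67.6%, 63.3%, 67.8% and 84.2%, against 36.0%, 38.2%, 41.5% and 48.4%. With a reciprocal overlap of at least 50%, the shares of all regions were 43.4% and 35.5%, where shifted lists gave 10.4% and 8.46%.

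**Figure D2:**
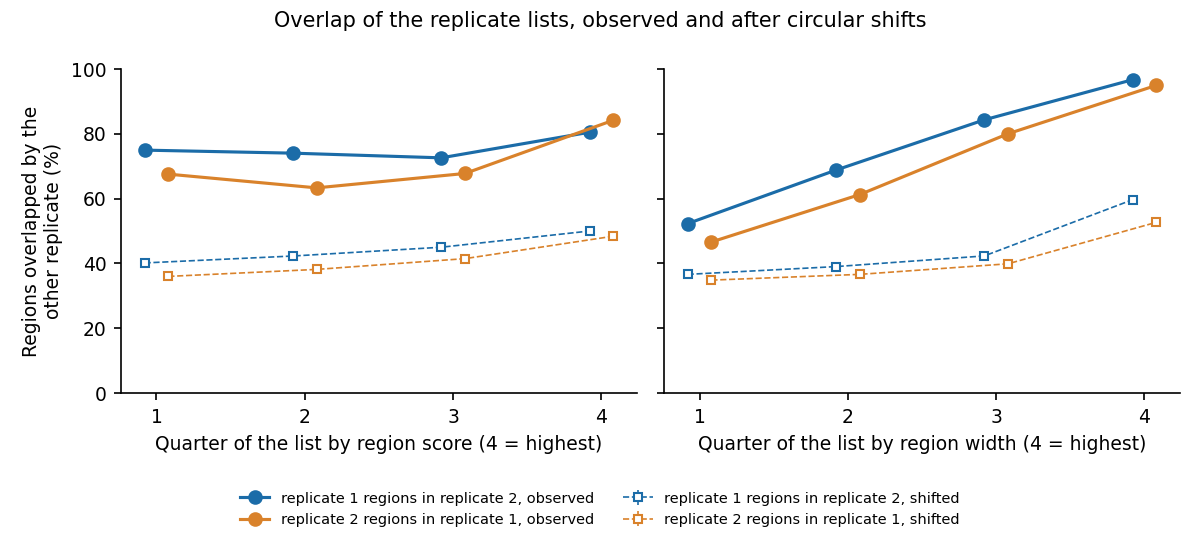
Percentage of regions overlapped by the other replicate (vertical axis) in 4 equal parts of each list by score (left) and by width (right), observed as filled circles and after 1000 circular shifts as open squares (mean, with SD bars that lie within the squares). By width the share in replicate 1 goes from 52.3% in the narrowest part to 96.7% in the widest, and all observed shares lie above the shifted ones.

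How far region scores repeated was examined over the 6128 pairs of overlapping regions. In these pairs a broad replicate 2 region could recur as partner of several replicate 1 regions. Wider regions scored higher within each list (Spearman coefficient 0.59 in both replicates). Recurring partners may therefore affect the shares and coefficients that follow, and their effect was not separated. Autosomal regions were scored lower in replicate 1 (median 0.67) than in replicate 2 (0.88), with the higher score in replicate 2 in 79.0% of 5021 pairs. On X the medians were 0.89 and 0.97, with the higher score in replicate 2 in 60.6% of 1016 pairs. Chromosome 4 went the other way, with medians of 0.99 and 0.79 and a higher score in replicate 2 in 32% of 50 pairs. Across all pairs the Spearman coefficient was 0.363 (95% interval 0.334 to 0.390) and Pearson's r was 0.421. The Spearman coefficient was 0.348 on the autosomes, 0.264 on X and 0.437 on chromosome 4. Among 3518 pairs with a reciprocal overlap of at least 50%, it was 0.557.

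**Figure D3:**
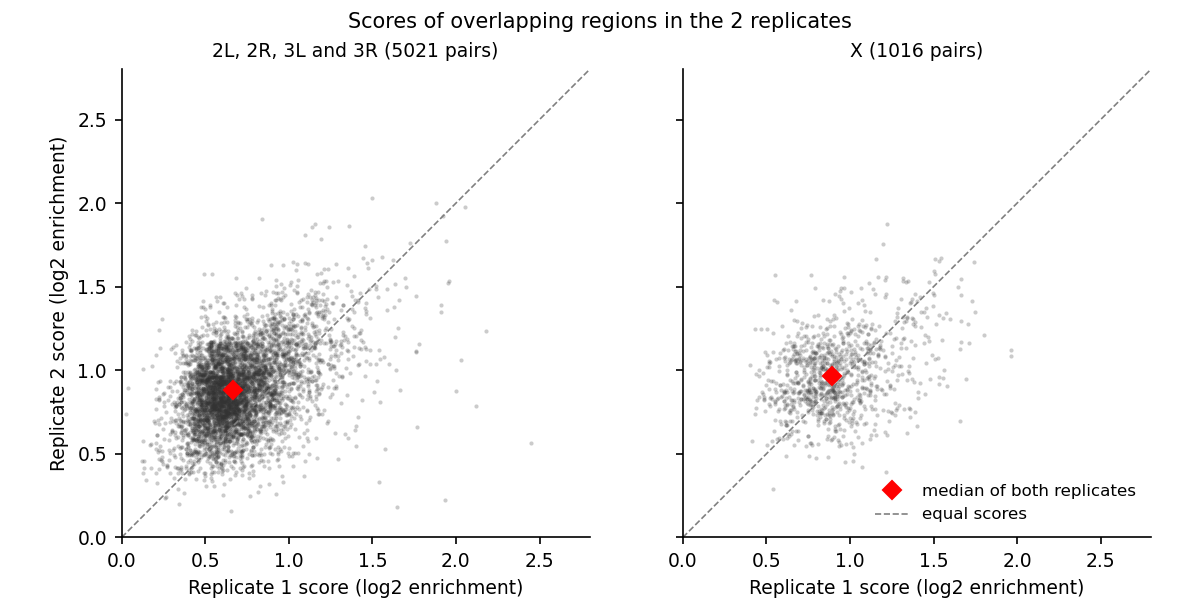
Scores of overlapping regions in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both as log2 enrichment, for autosomal pairs (left) and X-linked pairs (right), with the median as a diamond and equal scores as a dashed line. The autosomal median lies at 0.67 and 0.88 and the X-linked median nearer to the line, at 0.89 and 0.97.

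The combined list was compared with the replicates to see which of its regions each of them listed. Regions overlapped by both replicates numbered 4874 of 11016, or 44.2% (95% Wilson interval 43.3 to 45.2), and were wide, with a median of 4202 bp, so that they held 76.5% of the covered length. Replicate 1 alone overlapped 1774 regions (16.1%), replicate 2 alone 2152 (19.5%), and neither 2216 (20.1%), the last with a median width of 1217 bp. Support by both replicates went from 17.2% in the lowest 25% by score to 82.5% in the highest 25%, and from 1.20% in the narrowest 25% to 94.9% in the widest 25%. These shares were not compared with shifted lists, and wide regions are overlapped more often by position alone. Between the replicates, shifted lists overlapped 73.3% and 67.7% of regions of at least 10 kb. Score followed width in the combined list (Spearman coefficient 0.513), so the 2 trends were not separated. By arm, X had 38.8% of its 2250 regions supported by both replicates and 26.2% by replicate 1 alone, whereas the autosome arms had 43.4% to 48.2% supported by both and 12.6% to 13.8% by replicate 1 alone. In the reverse direction, 96.7% of replicate 1 regions and 92.0% of replicate 2 regions were overlapped by a combined region. High shares were likely beforehand, because the combined list stems from the same replicate set. Of the regions without overlap in the other replicate, 87.2% in replicate 1 and 73.3% in replicate 2 were also overlapped by a combined region.

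The very highest combined scores did not follow this trend with score. Of the 20 highest-scoring combined regions, 5 were overlapped by both replicates and 14 by neither, and of the 100 highest, 78 and 17. The 17 were between 1001 and 1107 bp wide. No replicate region was narrower than 1301 bp, and 60.3% of all combined regions without overlap in either replicate were narrower than that.

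Chromosomes were compared to see whether LSD1 regions were spread evenly. X-linked regions had higher scores than autosomal ones in both replicates. The median on X was 0.86 in replicate 1 and 0.93 in replicate 2, where the autosomes had 0.65 and 0.82. The difference was 0.21 (95% interval 0.19 to 0.23) and 0.11 (0.091 to 0.13), a mean of 0.16 ± 0.071 (SD, n = 2), and 0.14 (0.12 to 0.15) in the combined list. Among the upper 25% of combined regions by score it was −0.038. The lowest-terms denominators of the scores, taken per kb at their 80th percentile, stood on X at 0.538 times the autosomal value in replicate 1 and 0.699 times in replicate 2.

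The density of regions on X relative to the autosomes did not hold between the replicates. X had 73.8 regions per Mb in replicate 1 and 71.6 in replicate 2 (72.7 ± 1.58, SD, n = 2), and the autosomes had 65.2 and 84.8 (75.03 ± 13.8). The ratio of X to autosomes was therefore 1.13 (95% interval 1.01 to 1.26) in replicate 1 and 0.844 (0.756 to 0.938) in replicate 2. The combined list gave 1.13 (1.01 to 1.25), which was 2.36 among its upper 25% by score and 0.961 among regions overlapped by both replicates. Covered length gave ratios of 1.04, 0.689 and 0.971 in replicate 1, replicate 2 and the combined list. The covered share in replicates 1 and 2 was 27.8% and 20.4% on X, and 26.8% and 29.6% on the autosomes. By covered length the replicates thus lay further apart on X, and by number of regions further apart on the autosomes.

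Chromosome 4 had fewer regions per Mb than the autosomes in replicate 2 (47.3 against 84.8) and about as many in replicate 1 (63.6 against 65.2). The ratio was 0.975 in replicate 1, 0.558 in replicate 2 and 0.706 in the combined list, and 1.41 among the upper 25% of combined regions by score. Its median score differed from the autosomes by 0.20 in replicate 1 and −0.069 in replicate 2, so that no direction held. Het contigs had few listed regions per Mb of full length, 5.82 in replicate 1 and 4.42 in replicate 2 (5.12 ± 0.990, SD, n = 2). The autosomes had 65.2 and 84.8. Their median scores were 1.03 and 0.78, above the autosomes in replicate 1 and below them in replicate 2. The unplaced sequence U had 1.69 and 0.796 regions per Mb, and YHet and Uextra had 0 regions in every list. The part of these sequences that reads could align to is not given in the sources used here. Low values there therefore do not show that LSD1 was depleted.

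**Figure D4:**
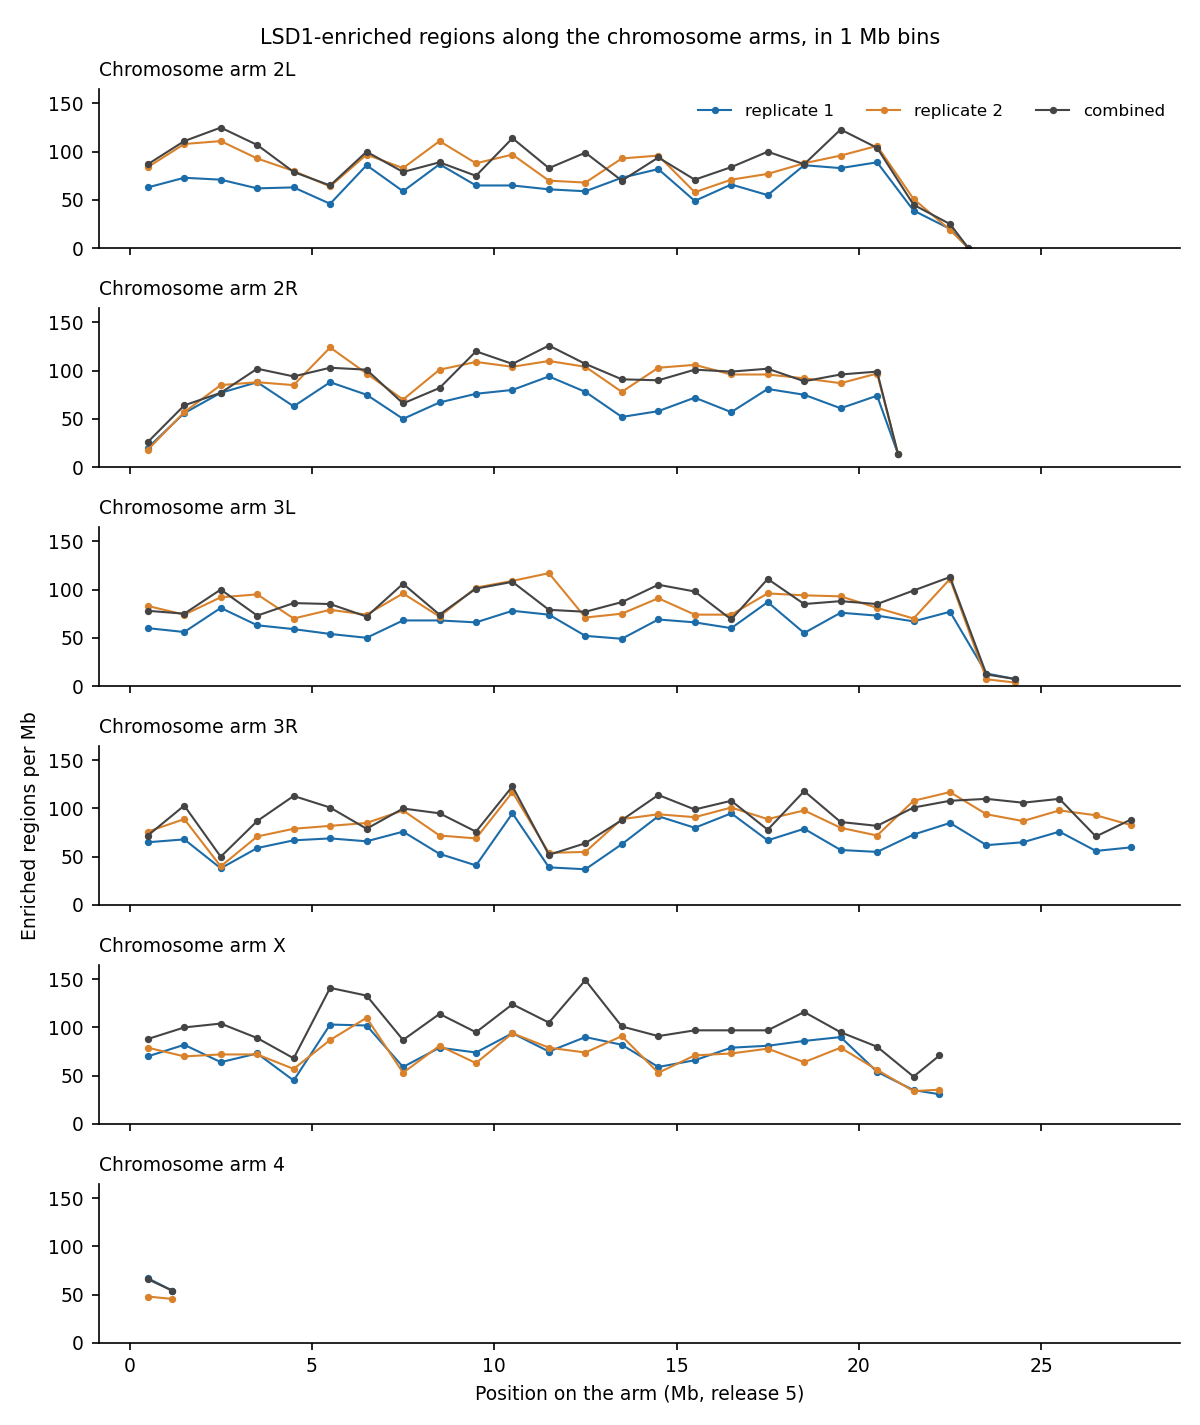
Enriched regions per Mb (vertical axis) in 1 Mb bins along the 6 chromosome arms (position in Mb on release 5, horizontal axis), with lines for replicate 1, replicate 2 and the combined list. In number of regions, replicate 2 runs above replicate 1 over most of the autosome arms (84.8 against 65.2 per Mb) while both run together on X (71.6 and 73.8). Covered length, which is not drawn, differed more on X (27.8% in replicate 1 and 20.4% in replicate 2) than on the autosomes (26.8% and 29.6%).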

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

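The restriction of overlap and score agreement to autosome arms and the minimum width for combined regions were chosen after the results were seen. Replicate overlap stayed above the shifted lists, with a one-sided permutation p of 0.001 (the smallest they can give), under 14 of 14 alternatives, at 43.4% to 79.7% of replicate 1 regions and 35.5% to 70.7% of replicate 2 regions. Of all 44 alternatives, 28 were counted as keeping the result, 10 moved the value without turning its direction and 6 turned its direction. The 28 include the 14 for overlap, which kept their side of the threshold although most of their values moved. The others stayed within the limits of error. For X and chromosome 4 these limits were the SD of the same 2 replicates, for example 0.295 for the chromosome 4 ratio. Values of single replicates were thus judged against a spread made from them, which is a weak check. The Spearman coefficient between scores moved to 0.399 with pairing by highest score and to 0.557 with reciprocal overlap of at least 50%; the cause was not tested. Support by both replicates moved to 35.3% when 50% of the region had to be overlapped, by construction a stricter rule, to 65.9% and 82.5% among the upper 50% and 25% by score, and to 54.9% among regions at least as wide as the narrowest replicate region. The ratio of X to autosomes in regions per Mb moved to 2.10 and 2.36 among the upper 50% and 25% by score, and turned to 0.971 with covered length and 0.961 among regions overlapped by both replicates, and single replicates gave 0.844 to 1.13. The ratio of chromosome 4 to autosomes turned to 1.41 among the upper 25% by score, with 0.558 to 0.975 in single replicates. The score difference of X to autosomes moved to 0.024 and turned to −0.038 among the upper 50% and 25% by score, subsets that by construction leave out low scores on every arm, and single replicates gave 0.11 to 0.21. That of chromosome 4, 0.057 in the combined list, ranged from −0.069 to 0.20 in single replicates and was 0.18 and 0.14 among the upper 50% and 25% by score and 0.22 among regions overlapped by both replicates; the cause was not tested for these ratios and differences beyond the closing observations. No paired analysis was possible because the replicate numbers shared by ChIP and input enter only through lists already called against the input of the same number, and values per input library were not used here. Alternatives for position relative to genes, promoter occupancy and gene class were not run, because the supplied gene table follows release 6, not release 5. Depth per library is not given in the sources used here, which leaves open how much of the difference between the lists is counting error.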

Other observations

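The tests and descriptions in this part were chosen after the results were seen, except the test of widths under the narrowest replicate region. Listed regions were fewer per Mb at the centromere-side end of the assembled sequence on most arms. In the 2 Mb at that end, 2L had 28.5 regions per Mb in replicate 1 and 33.5 in replicate 2. The rest of the arm had 68.8 and 87.7. The same part of 3L had 21.0 and 23.0 against 65.8 and 86.8, that of 2R 38.0 and 37.5 against 71.4 and 95.8, and that of X 40.0 and 41.5 against 77.1 and 74.5. The arm 3R was different: the 2 Mb at its centromere-side end had 66.5 and 82.5 regions per Mb, 1.01 and 0.968 times the rest. Of this sequence 34.2% and 35.8% was covered, where the rest of the arm had 26.4% and 30.0%. These differences were not tested beyond the comparison of the replicates. How much of each stretch reads could align to is not given in the sources used here. Fewer LSD1 regions therefore cannot be told apart from less alignable sequence.

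Over 118 bins of 1 Mb, the number of regions in replicate 1 and replicate 2 had a Spearman coefficient of 0.630 and a Pearson r of 0.733, and the Spearman coefficient was 0.766 over the 95 autosomal bins. These are correlations across bins of the genome, which are not independent replicates. The densest bin of the combined list was X from 12000001 to 13000000, with 149 regions, against a median of 95, and the sparsest was 3L from 23000001 to 24000000, with 12. The 3 entries typed as depletion lay at 2R:18693734-18695424, 3R:4769944-4771476 and 3R:5618204-5619904, with scores of −0.040, −0.14 and −0.0053. Enriched regions of replicate 2 overlapped all 3, and enriched regions of replicate 1 overlapped the second.

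X-linked regions scored higher than autosomal regions in both replicates, a pattern for which no biological explanation was tested, since the design compares no conditions. If fewer reads on X had only raised the score needed for a call, high-scoring regions would be no denser on X, yet in replicate 1 regions of 4 kb or more above the autosomal upper quartile of score were 2.52 times as dense on X (95% interval 2.08 to 3.03), which argues against this as the whole cause there. In replicate 2 the ratio was 1.08 (0.781 to 1.44), and the explanation stays open. A different share of X chromosomes in ChIP and input DNA may also raise X scores by a fixed amount, and the shift on X in replicate 1 was 0.072 larger at the 95th than at the 5th percentile of score (0.029 to 0.12). In replicate 2 the shift was 0.098 at the 5th and 0.13 at the 95th percentile and in the combined list 0.11 and 0.10, closer to a fixed amount, but chromosome 4 shifted by 0.20 and −0.069 in the replicates, so this too stays open.

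The highest combined scores belonged to narrow regions that neither replicate listed. A candidate explanation is few input reads under such scores: among the 100 highest-scoring regions, the median lowest-terms denominator was 1 in the 17 without support and 402 in 76 of the 78 with support from both replicates, the other 2 having no whole-number ratio (two-sided permutation p of 2e-05, the smallest that 100000 resamples can give). Another is the width that a list admits, since 100% of the 17 were narrower than 1301 bp, the narrowest region of either replicate. Among combined regions of at least that width, 54.9% were overlapped by both replicates and 9.94% by neither, so width does not account for all regions without support. Both tests came out as their explanations predict but on the same 17 regions, so their parts were not separated. The test of denominators cannot decide, because its outcome was likely beforehand. Denominators rose with width in the combined list (Spearman coefficient 0.694), the 17 were narrow, and all 100 regions were picked for high ratios. No biological explanation was tested.

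The whole numbers behind the scores, taken per kb at their 80th percentile, were lower on X than on the autosomes by different amounts in the replicates, with denominators at 0.538 and 0.699 times the autosomal value. If selection of regions with few input reads were the whole source, the gap should close in regions of 4 kb or more. There it was 0.177 (95% interval 0.116 to 0.209), which argues against this as the whole source. A part is left open, since the ratios of medians were 0.514 and 0.668 over all regions and 0.554 and 0.662 in regions of 4 kb or more. At the median the gap thus narrowed without closing, and no interval was computed for it. A different share of X chromosomes in the fly collections of the replicates, for example from different numbers of males and females, may be the source, but this stays open: the numerators showed a gap of the same sign, 0.142 (0.113 to 0.177), of which 0.133 already follows from the denominators and the median scores. It would not move chromosome 4, whose denominators over all regions also differed, by 0.395. The interval of 0.238 to 0.519 came from draws of single chromosome 4 regions (86 and 64). These are neighbours and not independent, so it may be too narrow. Selection was not checked there, as regions of 4 kb or more numbered only 17 and 8. If this gap holds, the part on chromosome 4 needs another explanation, and no biological explanation of it was tested. All of this assumes that denominators and numerators follow input and ChIP reads, which no header states.

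Autosomal denominators per kb at their 80th percentile were 91.9 in replicate 1, 44.4 in replicate 2 and 136.9 in the combined list. The combined value was thus 1.005 times the sum of the replicates. All sums in this paragraph are of such percentiles over regions, so they do not test whether values add up within single regions. Numerators gave 0.872 times the sum over all autosomal regions, which are not the same in each list. In 835 autosomal regions matched in all lists at a reciprocal overlap of at least 80%, denominators gave 1.003 and numerators 0.987 times the sum. This is consistent with a combined list called on the pooled reads of both replicates, a hypothesis that rests on the same reading of the whole numbers.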
